A study of Mus musculus with 2 samples.

How the data were processed

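Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 trimethylated at lysine 36 (H3K36me3) in the facial prominences of mouse embryos of the B6NCrl strain at 11.5 days of development. H3K36me3 is laid down by Setd2 along genes that RNA polymerase II is transcribing. Per the labels, there is 1 group with 2 biological replicates. Replicate 1 came from the pooled tissue of 109 embryos and has 3 technical replicates, and replicate 2 came from 88 embryos and has 1. Male and female embryos were mixed in each pool.

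The deposited data used here were 4 peak lists on the mm10 assembly, per the deposited text records. They hold the peaks of each replicate, the peaks the authors called on both replicates together (the pooled list), and a list the authors named replicated. The lists of replicate 1 and of the pooled replicates were derived from the filtered alignments and 2 further files, and that of replicate 2 from its alignments and 1 further file, per the deposited text records, which do not say what those files are. Aligner, peak caller, thresholds and the rule behind the replicated list are not given in the sources used here. Each peak has a start, an end, a summit and a signal value from the authors, whose scale is not stated and which was used only to rank peaks within a list. The deposited lists also give −log10 of a p-value and of a q-value for each peak. The lowest −log10 p was close to 2 in each list, and the q-values were not limited. Read depth is not given in these lists, so it is unknown, and no value here has a depth-based error. Read alignments, signal tracks and control libraries were not analysed here.

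All 23013 peaks of the replicated list have the position of a pooled-list peak. Of these, 9708 had at least 1 bp under peaks of both replicates, 10024 under peaks of replicate 1 only, 1857 under peaks of replicate 2 only and 1424 under neither. The list is therefore not a list of peaks found in both replicates, and values from the replicates' own lists are given beside it for many gene lists and named genes.

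Genes came from GENCODE release M21 for the same assembly, and chromosome lengths and GC content from the GRCm38.p6 sequence. No peak in any list ended beyond its chromosome. The analysis covered 21221 protein-coding genes of 1000 bp or longer on the autosomes, X and Y. A gene was called marked when at least 5% of its body, from annotated start to annotated end, lay under replicated peaks. Exons were the merged exons of protein-coding transcripts. Overlap between the replicates was the share of peaks with at least 50% of their length under peaks of the other replicate, with Wilson 95% intervals that cover counting error only. Chance was measured from 100 circular shifts of the peaks along their chromosomes.

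The ratio of coverage on the 3' side to that on the 5' side of the gene midpoint was taken over genes of 10 kb or longer, and the ratio of exonic to intronic coverage over marked genes. Each was computed per replicate and given as mean ± SD. The per-gene difference, averaged over the replicates, was tested with a two-sided permutation test of 100000 random sign flips. For 30 gene lists, the number of marked members was compared with 10000 random lists drawn from the same 10 bins of gene length, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 30 lists and a threshold of 0.05. The smallest p these tests can give is 1e-05 for sign flips and 2e-04 for lists before adjustment. Genes are not replicate embryos, so each p-value describes genes in these libraries. With a single group, no comparison between conditions was made.

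The tests, gene lists and alternatives were fixed before the data were examined, as was the rule for naming genes. It took the 3 members of each list with the largest percent covered and the 2 longest with no covered base, the 10 most covered genes of 10 kb or longer, and the 5 widest and the 5 highest-signal replicated peaks. It also took the 5 genes of 10 kb or longer that differed most between replicates in each direction, and 16 genes chosen in advance. Other names are said to have been chosen later. Alternatives covered the overlap rule, stricter p and q thresholds, coverage minimums, peak sets, gene length, gene ends, overlapping genes, matching and leaving out either replicate. Matching on GC content, leaving out X and Y and keeping replicated peaks seen in both replicates were added after seeing the data.

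The code was tested on simulated data. A simulated overlap of 40.1% was returned as 40.2%, a 3' to 5' ratio of 2 as 2.01, and an exon to intron ratio of 5.99 as 6.00. Among simulated lists of 25 genes, 42 of 100 lists enriched 3-fold and 1 of 100 unchanged lists were called above their matched lists. Of 100 lists with marking lowered to 0.25 of its level, 0 were called below. The simulation drew fewer random lists and adjusted over more lists than the test of the data, so these rates are not those of that test. A missing call for lists of that size was still taken to say little about depletion. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and figures used matplotlib.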

Results

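H3K36me3 was mapped in facial prominence tissue of mouse embryos at 11.5 days, when the neural crest mesenchyme and the ectoderm that will build the face are growing and patterning. The series holds 2 biological replicates of a single group. Replicate 1 had 70872 peaks that together covered 21.1 Mb, and replicate 2 had 16592 peaks covering 4.76 Mb. The authors' replicated list had 23013 peaks with a median width of 352 bp, covering 9.87 Mb or 0.362% of the genome. Read depth is unknown, because the deposited lists give peaks and no counts. A q-value of 0.01 or lower was reached by 29720 peaks in replicate 1, by 20 in replicate 2 and by 2526 in the replicated list.

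The mark lay almost wholly inside genes. Of the replicated peaks on chromosomes, 95.9% (Wilson 95% interval 95.6 to 96.1%) had their centre in a protein-coding gene, against 41.0% on average for peaks shifted along their chromosomes. The share was 92.4% in replicate 1 and 96.0% in replicate 2. Few peaks lay at gene starts, with 0.483% of replicated peaks centred within 1 kb of the start of a protein-coding gene (interval 0.401 to 0.581%), against 1.70% after shifting. A further 3.52% lay in no annotated gene, against 52.2% after shifting.

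The widest replicated peak spanned 8742 bp at chromosome 1, 88261524 to 88270265, with its summit in an exon of Hjurp, the chaperone that deposits the centromeric histone CENP-A. A peak of 5432 bp lay over exonic sequence of Srrm2, a nuclear speckle protein involved in splicing (chromosome 17, 23814638 to 23820069). Prrc2a held a peak of 3939 bp (chromosome 17, 35155375 to 35159313), and zinc finger genes held the other 2 of the 5 widest. Zfp354c held a peak of 3987 bp at chromosome 11, 50813928 to 50817914, and Zfp865 held one of 4111 bp at chromosome 7, 5028624 to 5032734, where it also lay in introns of Ccdc106 and Gm44973. Both had their summits in Zfp exons. By the authors' signal value, the 5 highest peaks had their summits in exons of 2610008E11Rik, Zfp354c, Zfp865, Zfp763 and Zfp157.

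How far the replicates shared their peaks was compared by overlap. Of the 16592 peaks of replicate 2, 8177 or 49.3% (Wilson interval 48.5 to 50%) had at least 50% of their length under replicate 1 peaks. Shifted peaks gave 0.901% on average and at most 1.22%. In the other direction, 6213 of the 70872 peaks of replicate 1 were covered by replicate 2, or 8.77% (8.56 to 8.98%), against 0.20% after shifting. Replicate 1 had 4.27 times as many peaks, which limits the share of its peaks that the shorter list can cover. Taking the same number of top peaks from each replicate gave 24.0% of replicate 2 peaks and 15.9% of replicate 1 peaks.

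At the level of genes, replicate 2 was nearly contained in replicate 1. Each replicate's own peaks marked 4814 genes in replicate 1 and 1302 in replicate 2, and 1279 genes were marked in both. That is 98.2% of the genes marked in replicate 2, against 295.4 genes expected from independent lists. Across the 10172 genes with a covered base in either replicate, percent covered had a Spearman rho of 0.669 and a Pearson r of 0.762 between replicates. These correlations are across genes, which are not independent replicates.

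By the replicated list, 2552 of 21221 protein-coding genes (12%) were marked, with a median of 10.9% of the gene body covered. The most covered gene of 10 kb or longer was Prrc2a in the major histocompatibility region (chromosome 17, 35149076 to 35164897), with 70.2% under replicated peaks and 57.5% ± 6.90 over the replicates (SD, n = 2). Hjurp followed with 69.8% and 61.8% ± 9.57 (SD, n = 2), and Fasn, which encodes fatty acid synthase, with 64.2% and 47.5% ± 7.27 (SD, n = 2). The remaining genes among the 10 most covered were the zinc finger genes Zfp606, Zfp90 and Zfp110, the RNA helicase gene Ddx39b, the condensin subunit gene Ncapd2, the translation initiation factor gene Eif4g2 and the transcription factor gene Tcf3. Their coverage ran from 54.6% for Zfp110 to 62.6% for Zfp606. The count of marked genes depended on the coverage minimum and the peak set. With any covered base it was 5610, and with replicated peaks that lay under peaks of both replicates, an alternative added after seeing the data, it was 1435. The share of marked genes also varied with gene length. It was 20.1% in the length bin with a median of 15.5 kb and 1.13% in the longest of the 10 bins. In that longest bin 22.9% of genes had a covered base.

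**Figure D1:**
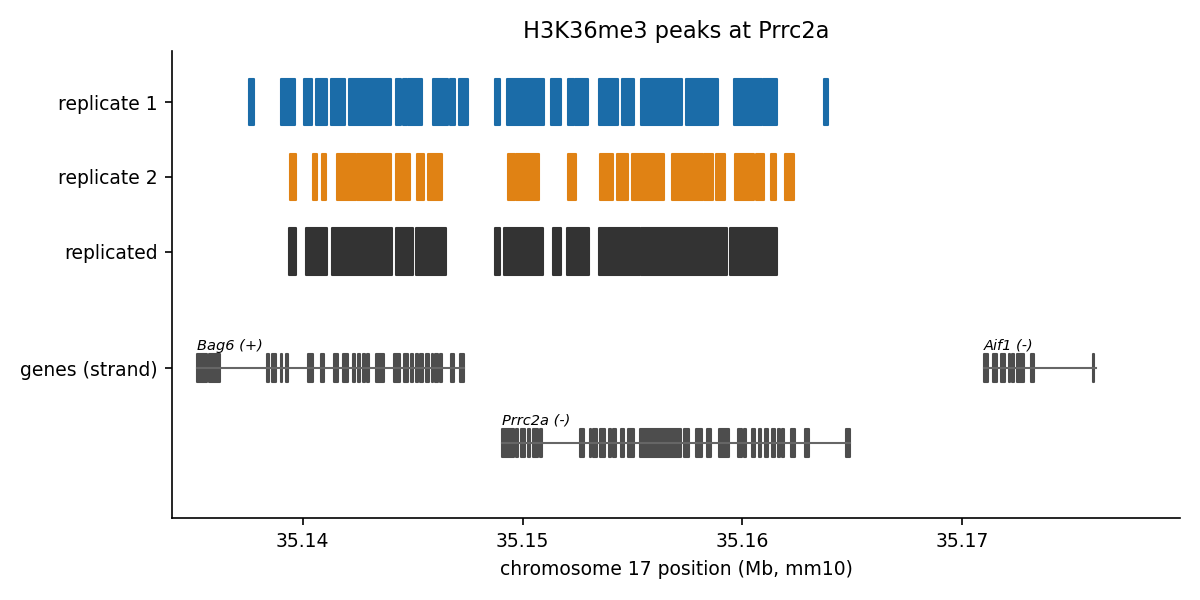
Map of the Prrc2a region on chromosome 17 (mm10, position in Mb): each bar is a peak of replicate 1, of replicate 2 or of the replicated list, and boxes on lines are merged exons of protein-coding genes with their strand. Peaks of all 3 lists covered most of Prrc2a (70.2% by the replicated list) and stopped short of its start at the right, and the macrophage gene Aif1 beside it had no peak.

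Genes were ranked by the difference in percent covered between the replicates. Peaks of replicate 1 covered 4.43 times as many bases in total as those of replicate 2. A large difference in favour of replicate 1 therefore does not by itself set a gene apart. Ncapd2 had 54.3% of its body covered in replicate 1 and 19.4% in replicate 2. Prmt1, an arginine methyltransferase gene, had 45.2% and 11.5%, and the splicing factor gene Prpf8 42.6% and 9.90%. Ddx47 and Flii completed the 5 largest differences in this direction. In the other direction the largest difference was at Ubtf, an RNA polymerase I transcription factor gene, with 3.37% in replicate 1 and 7.94% in replicate 2. Gm20521, Selenon, Ilf2 and Surf4 followed. No test of a single gene is possible with 2 replicates of a single group.

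Coverage increased along genes towards the 3' end. In 14164 genes of 10 kb or longer, peaks covered 2.32 ± 0.34 times as many bases on the 3' side of the gene midpoint as on the 5' side (mean ± SD, n = 2 replicates). The ratio was 2.08 in replicate 1, 2.56 in replicate 2 and 2.56 in the replicated list. More was covered on the 3' side in 6259 genes and on the 5' side in 2147, while 5758 were equal. The two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 sign flips can give. In replicate 1, 0.389% of bases were covered in the first 5% of the gene body and 3.38% in the part with the highest coverage inside genes, and coverage stayed at 3.57% over the 2 kb past the gene end.

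**Figure D2:**
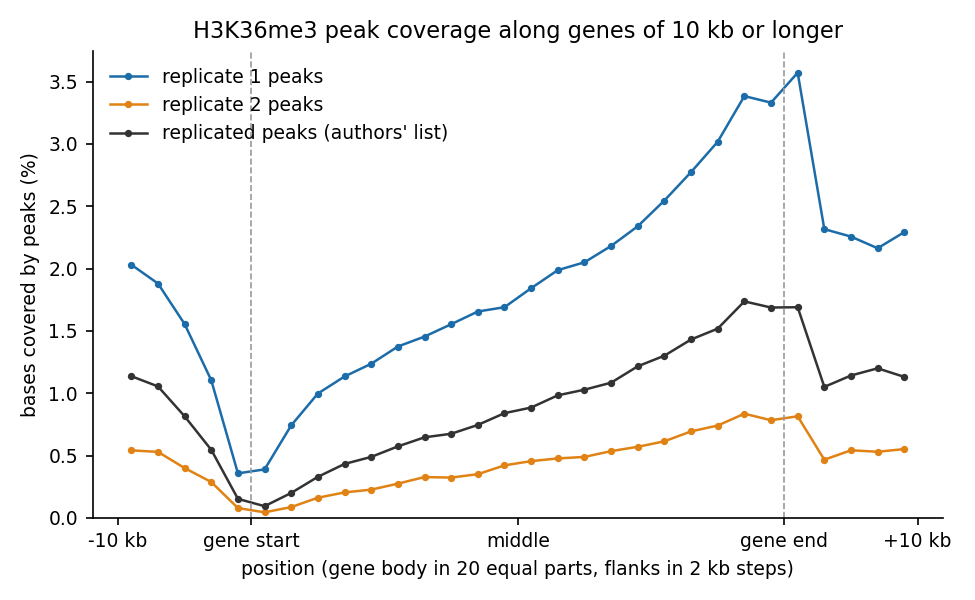
Percent of bases covered by peaks (vertical axis) along 14164 genes of 10 kb or longer, with the body in 20 equal parts and 10 kb of flank on each side, for replicate 1, replicate 2 and the replicated list. Every line has its minimum close to the gene start and rises towards the gene end, with a 3' to 5' ratio of 2.08 in replicate 1 and 2.56 in replicate 2, and flanks include neighbouring genes.

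Exons carried more of the mark than introns of the same genes. In marked genes, 26.4% of exonic and 14.6% of intronic bases were covered in replicate 1, and 11.4% and 4.80% in replicate 2. The exon to intron ratio was 2.10 ± 0.40 (mean ± SD, n = 2), and 2.24 by the replicated list. It was taken on bases pooled over the marked genes and not within each gene. Of 2543 marked genes with exons and introns, 1878 had more of their exonic and 660 more of their intronic sequence covered (two-sided permutation test over genes, p = 1e-05, the smallest possible). Comparing windows of 200 bp within bins of similar GC content, added after seeing the data, gave a ratio of 2.10. Such windows fit only in exons of 200 bp or longer, so shorter exons were left out. Position along the gene was not matched either, so this value does not separate exons from the rise in coverage towards the 3' end. Over all protein-coding genes, marked or not, the ratio was 5.07, so its size depends on the genes taken.

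Which functions the marked genes serve was examined with 30 gene lists matched on gene length, of which 9 lay above and 6 below their matched lists. Genes of the general machinery of dividing cells were marked most often. Among 26 splicing factor and hnRNP genes, 23 were marked against 4.00 in matched lists, led by Prpf8 (40.2% covered), Hnrnpl (40.1%) and Sf3a1 (33.9%). DNA replication and cell cycle genes were marked in 20 of 26 cases against 4.01, with the cyclin-dependent kinase genes Cdk4 at 43.8% and Cdk1 at 36.4% and the topoisomerase gene Top2a at 30.6%. Translation factor and ribosome biogenesis genes followed with 16 of 22 against 3.61, including Eif4g2 at 56.2%, the elongation factor gene Eef2 at 39.5% and Eif4g1 at 32.3%. In replicates 1 and 2 alone, 25 and 17 splicing genes, 24 and 13 replication genes and 20 and 11 translation genes were marked. Coverage was lower in replicate 2, with 9.90% at Prpf8, 16.6% at Sf3a1, 23.9% at Cdk4, 15.3% at Cdk1, 15.6% at Top2a, 24.8% at Eef2 and 14.7% at Eif4g1. Each of these lists had an adjusted permutation p of 0.000667, which comes from the smallest p that 10000 lists can give before adjustment. Eef1a1, the other elongation factor gene of this list, had no covered base in either replicate.

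Ribosomal protein genes, which are short, were marked in 51 of 76 cases against 6.41 (adjusted permutation p = 0.000667), with Rps5 at 55.3%, Rps3 at 48.1% and Rps19 at 44.7%. Replicates 1 and 2 alone marked 57 and 33 of them, and in replicate 2 Rps3 had 13.4% and Rps19 17.6% covered. Chromatin regulator genes were marked in 18 of 29 cases against 2.01, with the same adjusted permutation p. Their leading members were the H3K4 methyltransferase gene Kmt2d (48.3%) and the remodeller genes Chd4 (40%) and Smarca4 (25.2%). Replicates 1 and 2 alone marked 23 and 11 of these genes, and in replicate 2 the 3 had 25.4%, 16.9% and 10.3% covered. Proteasome genes were marked in 12 of 26 cases against 3.69 (adjusted permutation p = 0.000667), led by Psma7 at 37.8%, with 16.2% in replicate 2. Replicates 1 and 2 alone marked 23 and 9, and their call was lost at a coverage minimum of 10% (6 against 2.04) and when only replicated peaks under peaks of both replicates were kept (6 against 2.10). Oxidative phosphorylation genes were marked in 9 of 25 cases against 3.89 (adjusted permutation p = 0.0454). Atp5a1 had 43.8%, Cyc1 27.1% and Ndufb8 22.9% covered, the last with 3.20% in replicate 2. Replicate 1 alone marked 20 of the 25. The call was lost in replicate 2 alone (4 against 2.10), at a minimum of 10% (6 against 2.26), with replicated peaks under peaks of both replicates (6 against 2.33) and without overlapping genes (6 of 16 against 2.14), with fewer marked genes in each of these.

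Zinc finger protein genes with Zfp symbols were the largest list above its matched lists. Of 391 members, 138 were marked against 60.2 (adjusted permutation p = 0.000667), and replicate 1 alone marked 198 and replicate 2 alone 95. Zfp606 (62.6%), Zfp90 (58.8%) and Zfp358 (56.0%, with 35.4% in replicate 2) were covered most, while the long genes Zfp804b and Zfp385b had no covered base in any list. How reads shared between related copies were handled is not given in the sources used here. With the last exon, which usually encodes the zinc finger array, left out of every gene, 82 of 385 were marked against 54.7. Clustered protocadherin genes, whose gamma members share their 3' exons, were marked in 9 of 57 cases against 3.41 (adjusted permutation p = 0.0289). The nested members share the same covered bases and count several times. Pcdhgc5, Pcdhga9 and Pcdhga8 had 5.49 to 5.82% covered, with 10.8 to 11.9% in replicate 1 and 2.41 to 2.58% in replicate 2. Replicate 1 alone marked 21 of 57. The call was lost in replicate 2 alone (0 of 57), at a minimum of 10% (0 of 57), with replicated peaks under peaks of both replicates (0 of 57) and without length matching (9 against 6.84, adjusted permutation p = 0.535). With overlapping genes left out too few members remained for a test.

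**Figure D3:**
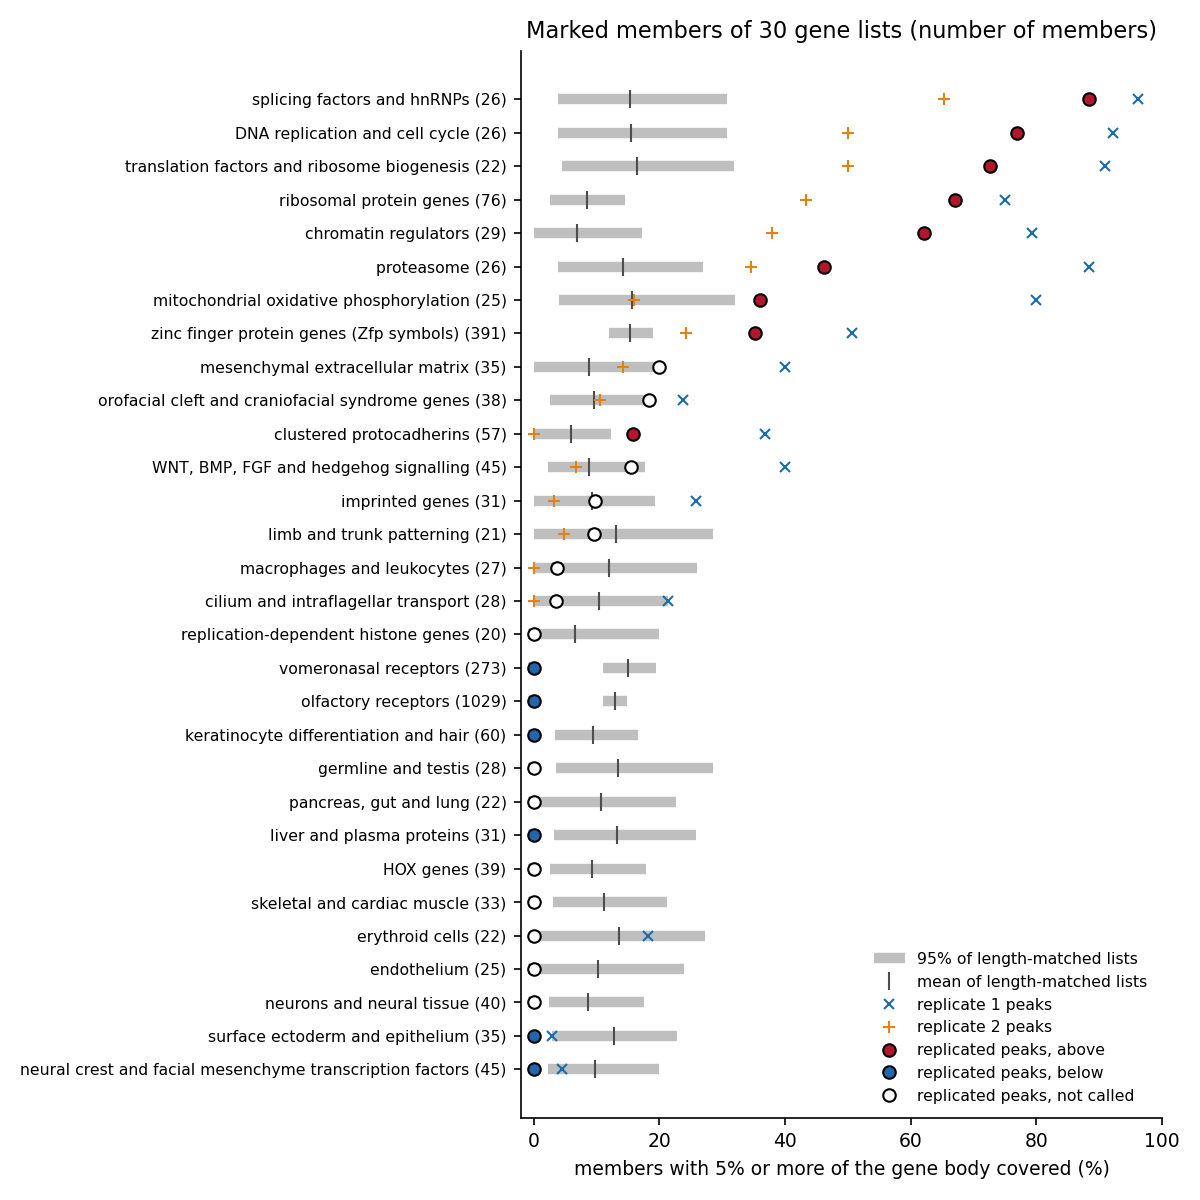
Percent of members marked (horizontal axis) in each of 30 gene lists, with the number of members in parentheses: circles are the replicated list (red above, blue below, white not called), crosses and plus signs are the peaks of replicates 1 and 2, and grey bars hold 95% of length-matched lists for the replicated peaks. Splicing, replication, translation, ribosomal protein and chromatin genes stand at 62.1 to 88.5%, and symbols of many tissue-specific lists coincide at 0.

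Genes of the facial programme itself were less uniform. None of the 45 neural crest and facial mesenchyme transcription factor genes reached 5% coverage, against 4.41 in matched lists (0 of 45, adjusted permutation p = 0.0438). Alx4, a regulator of craniofacial growth, had 1.93%, and the E-protein genes Tcf4 and Tcf12 had 1.2% and 1.11%. In replicates 1 and 2 these were 2.96% and 0.493% for Alx4, 2.38% and 0.396% for Tcf4, and 2.20% and 0.630% for Tcf12, and 2 and 0 members were marked. Counting any covered base, 9 of 45 had a peak against 9.93, and the list was not called (adjusted permutation p = 0.932), so its call rests on the extent and not the presence of peaks. Msx1 and Twist1 had no covered base in either replicate. Prrx1 had 0.340% covered by the replicated list, with 1.17% in replicate 1 and 1.57% in replicate 2. The long genes Sox6 and Runx2 had none by the replicated list.

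Mesenchymal extracellular matrix genes were marked in 7 of 35 cases against 3.10, which did not pass the threshold (adjusted permutation p = 0.0825). The list was above matched lists by any covered base (20 of 35 against 11, adjusted permutation p = 0.00500), at a minimum of 10% (6 against 1.44, 0.0107), with pooled peaks (12 against 4.60, 0.00386), in replicate 1 alone (14 against 6.46, 0.00570) and by median coverage (0.00540). Serpinh1, the collagen chaperone gene, had 42.7% covered, the cartilage collagen gene Col2a1 38.5% and the fibronectin gene Fn1 17.9%. In replicate 2 Serpinh1 had 22.6% and Col2a1 24.0%. Replicates 1 and 2 alone marked 14 and 5 members. Col3a1 had 0.582%, with 1.87% in replicate 1 and 0 in replicate 2, and Lama4 and Col4a2 none by the replicated list. WNT, BMP, FGF and hedgehog signalling genes were marked in 7 of 45 cases against 3.96 (adjusted permutation p = 0.203), and had a covered base in 23 of 45 against 12.9 (adjusted permutation p = 0.00388). They were also above in replicate 1 alone (18 against 7.92, adjusted permutation p = 0.00120) and by median coverage (0.000857). Ctnnb1, encoding beta-catenin, had 21.6%, the WNT feedback gene Axin2 13.8%, the hedgehog receptor gene Ptch1 12.8% and Fgfr1 4.74% covered. In replicates 1 and 2 these were 20.1% and 10.6% for Ctnnb1, 23.7% and 4.57% for Axin2, 13.7% and 5.11% for Ptch1, and 10.1% and 3.26% for Fgfr1, and 18 and 3 members were marked. Ror1 and Bmpr1b had none by the replicated list, with 0.109% and 0.30% in replicate 1. Among 38 genes of orofacial clefts and craniofacial syndromes, 7 were marked against 3.65 (adjusted permutation p = 0.164). Kmt2d, Col2a1 and the RNA polymerase subunit gene Polr1c (31.9%, with 15.3% in replicate 2) led them, replicates 1 and 2 alone marked 9 and 4, and Trp63 and Col11a1 had no covered base by the replicated list.

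Epithelial genes lay below their matched lists. In the surface ectoderm and epithelium list, 0 of 35 were marked against 4.45 (adjusted permutation p = 0.0360), and Lama5, at 3.05% and with 0.533% in replicate 2, was the single member with a replicated peak. The keratinocyte differentiation and hair list had 0 of 60 marked against 5.70 (adjusted permutation p = 0.0162). Liver and plasma protein genes had 0 of 31 against 4.12 (adjusted permutation p = 0.0456), with Alb at 0. Olfactory receptor genes had 0 of 1029 against 133.5 and vomeronasal receptor genes 0 of 273 against 40.9, each with an adjusted permutation p of 0.000667. As for the Zfp genes, how reads shared between related copies were handled is not given, so missing peaks in these receptor genes may reflect missing reads. The epithelial, keratinocyte, liver and neural crest calls were lost at a coverage minimum of 10%, in replicate 2 alone, without overlapping genes and with replicated peaks under peaks of both replicates. Each list still had 0 marked members in these settings, while matched lists had fewer, from 2.12 to 4.20. The liver call was also lost without length matching (0 against 3.70), and a test of medians was void, since matched medians are 0.

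Several lists of other cell types had no marked member and did not pass the threshold at 5% coverage. They were neurons and neural tissue (0 of 40), endothelium (0 of 25), erythroid cells (0 of 22), skeletal and cardiac muscle (0 of 33), HOX genes (0 of 39), pancreas, gut and lung (0 of 22) and germline and testis (0 of 28). By any covered base, all of these except the erythroid list lay below matched lists, with adjusted permutation p from 0.000500 to 0.0117, and the same lists lay below in replicate 1 alone at 5% coverage. At that minimum, neurons, endothelium, muscle, HOX and germline genes also lay below with pooled peaks, neurons and HOX genes without length matching, and neurons (adjusted permutation p = 0.0413), muscle (0.0189), HOX (0.0220) and germline genes (0.0455) with matching on length and GC, which was added after seeing the data. Rbfox1, Nrxn1, Ryr2, Ttn, Hoxa3 and Olig2 had no covered base by the replicated list. Hoxa2 and Hoxb4, regulators of hindbrain and branchial arch identity, had none in either replicate. Replication-dependent histone genes had 0 of 20 marked against 1.30, cilium and intraflagellar transport genes 1 of 28 against 2.92, and imprinted genes 3 of 31 against 2.88. None of these 3 lists passed the threshold, with adjusted permutation p of 0.549, 0.433 and 1. The leading imprinted genes were Nnat (26.6%), Gnas (6.30%) and Mest (5.0%), all overlapping other coding genes, and the marked cilium gene was Kif7 (8.85%). Replicates 1 and 2 alone marked 8 and 1 imprinted genes, with 43.1% and 14.4% covered at Nnat, and 6 and 0 cilium genes, with 16.6% and 2.84% covered at Kif7.

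Some covered markers of other cell types lay beside a marked gene and others did not. Macrophage and leukocyte genes had 1 of 27 marked against 3.25 (adjusted permutation p = 0.321), and lay below in replicate 1 alone (1 against 5.94, adjusted permutation p = 0.0230). The marked gene was Cd68, with 36.4% covered, 38.6% in replicate 1 and 0 in replicate 2. It begins 0.782 kb past the 3' end of Eif4a1, which had 28.0% covered. Limb and trunk patterning genes had 2 of 21 marked against 2.77 (adjusted permutation p = 0.967). Tbx6 had 12% covered, with 17.1% in replicate 1 and 15.9% in replicate 2. It lies 0.305 kb past the 3' end of Ppp4c, which had 37.6% covered. Gdf11 had 7.5%, with 11.7% in replicate 1 and 0 in replicate 2, and its nearest coding gene, Sarnp, lies 4.67 kb away and had 0.381% covered. The erythroid gene Nfe2, with 4.90% covered and 9.16% in replicate 1, lies 1.52 kb past the 3' end of Hnrnpa1, which had 22.6% covered. Epb41, Epor and Tfrc reached 5% in replicate 1 only, and the coding gene that Epb41 overlaps and those nearest to the other 2 had no covered base by the replicated list. These neighbours were looked up after the values were seen.

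Among the genes chosen in advance, the H3K36 methyltransferase genes Setd2 and Nsd1 had 7.40% and 9.64% covered, with 9.01% ± 4.89 and 10% ± 8.30 over the replicates (SD, n = 2). Actb had 14.9% covered, and Gapdh 0.926%, with 5.55% in replicate 1 and 0 in replicate 2. Some covered genes named by the rule set in advance overlap another coding gene, whose peaks cannot be separated from theirs. They include Epb41, Cdk4, Atp5a1, Ndufb8, Ctnnb1, Alx4, Flii, Gm20521, Ilf2, Surf4, Kif7 and Gapdh.

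The X chromosome stood apart from the autosomes, a comparison made after seeing the data. Of 877 X-linked genes 3 were marked, or 0.342% (Wilson interval 0.116 to 1.00%), against 2549 of 20181 autosomal genes or 12.6% (Fisher's exact test, two-sided, p = 3.76e-45). Replicate 1 alone marked 29 X-linked genes, or 3.31%, against 23.7% of autosomal genes, and replicate 2 alone 1, or 0.114%, against 6.45%. The marked X genes were the filamin gene Flna (13.8%), the H3K4 demethylase gene Kdm5c (6.48%) and Gm21887 (16.8%), which lies beside Mid1 at the far end of the chromosome. The replicated peaks picked as the strongest on the X all lay at that end. Those starting at 169988500 and 169989762 had their summits in exons of Mid1, and that at 170011044 in an intron of Gm21887. In replicates 1 and 2 Flna had 22.7% and 3.13% covered, Kdm5c 11.6% and 0.944%, and Gm21887 19.3% and 8.64%. With any covered base, replicate 1 had a peak in 19.2% of X genes and 49.3% of autosomal genes, and replicate 2 in 1.60% and 23.7%. Among autosomes, the share of marked genes ran from 7.67% on chromosome 14 to 16.9% on chromosome 11. No gene of the 163 on Y was marked (0 of 163).

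**Figure D4:**
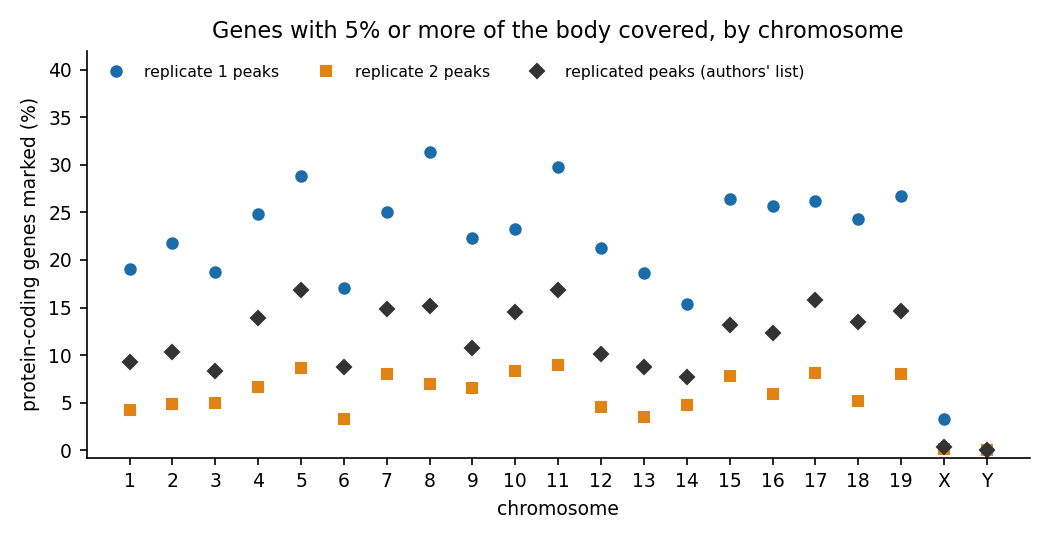
Percent of protein-coding genes marked (vertical axis) on each chromosome (horizontal axis), for the peaks of replicate 1, of replicate 2 and of the replicated list. By the replicated list the autosomes lie between 7.67 and 16.9% and the X at 0.342%.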

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

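Both counts in this part, their shifted-peak comparison and the neighbouring genes were chosen after the data were seen. At first the lincRNA count was to be listed only if it exceeded that of shifted peaks. It did not, and that condition was then dropped, so the count is listed solely for lying above the 3 that a count of 0 allows. Of 4963 lincRNA genes of 1000 bp or longer that overlap no protein-coding gene, 11 were marked by replicated peaks, or 0.222%. Shifted peaks marked 95 on average, but genes outside protein-coding genes were selected and 95.9% of replicated peaks are centred in protein-coding genes, so that comparison says nothing about lincRNA genes. The most covered, named after their values were seen, were Malat1 at 35.8%, a nuclear speckle RNA gene (chromosome 19, 5795690 to 5802672), Snhg12 at 35.0%, a small nucleolar RNA host gene, and Mir17hg at 29.3%, the host of a microRNA cluster. In replicates 1 and 2, Malat1 had 26.1% and 14.3% covered, Snhg12 33.9% and 14.5%, and Mir17hg 12.3% and 18.9%. Snhg12 lies 0.738 kb past the 3' end of the coding gene Trnau1ap, Lsmem2 0.455 kb past that of Ifrd2 and Gm43913 0.499 kb past that of Sinhcaf. The last 2 had no covered base in replicate 2.

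On unplaced or unlocalised scaffolds, which no comparison above uses, the replicated list had 10 peaks, also above the 3 that a count of 0 allows. They lay on 4 scaffolds. Replicate 1 had 41 such peaks and replicate 2 had 6. No explanation was tested for either count.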

How the results depend on the processing

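Alternatives matching on GC content, leaving out X and Y, and keeping replicated peaks under peaks of both replicates were chosen after the data were seen. The 3' to 5' ratio stayed between 2.05 and 2.92, the exon to intron ratio between 1.82 and 5.29 and the number of lists above between 6 and 11 under every alternative run. The share of replicate 2 peaks covered by replicate 1, 49.3%, became 63.5% at 1 bp, 31.4% at 80%, 29.8% reciprocally, 73.2% and 95% with p and q thresholds (448 and 20 peaks) and 24.0% with equal numbers. The share of replicate 1 peaks, 8.77%, became 14.9%, 3.46%, 6.97%, 0.956%, 0.0505% and 15.9% in the same order. The p and q thresholds left 29720 replicate 1 peaks each, which by itself limits that share. Of marked genes, 2552, there were 5610 with any covered base, 1401 at 10%, 518 at 20%, 637 from the intersection of the replicates, 488 at the q threshold, 1435 with peaks under both, and 1302 to 4814 leaving out a replicate, as stricter rules must give fewer. Lists below, 6, numbered 11 with any covered base, 11 with pooled peaks, 10 with GC matching, 2 each at 10%, without overlapping genes and with peaks under both, 2 to 13 leaving out a replicate, and 0 by median, where matched medians are 0 and the test is void. Clustered protocadherins, above by 9.80 percentage points, turned to −3.26 at 10%, −3.21 with peaks under both, and −2.97 to 24.2 leaving out a replicate; the cause was not tested, and too few remained without overlapping genes. Imprinted genes, not called under any alternative and 0.377 points above, turned to −1.67 at 10%, −2.38 without length matching, −0.0952 with 20 length bins, −8.05 without overlapping genes, −0.999 with GC matching and −1.29 to 7.04 leaving out a replicate, and cilium genes, 6.87 points below and not called, to 1.15 with any covered base. Of the other comparisons of lists, 255 kept their side of the threshold, 242 of them with their direction and 13 with no difference, 32 passed it and 32 no longer did. Depth is unknown, so whether uncovered genes lack the mark or reads cannot be decided.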

Other observations

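The comparison of the X with the autosomes, the test of a single active X copy, the X test within each replicate, the interval in the tissue make-up test, the GC-matched test of Zfp genes, and the positions of peaks past gene ends, in last exons and by chromosome were chosen after the data were seen. Replicated peaks outside annotated genes lay just past genes. Of the 809 replicated peaks centred in no annotated gene, 775 or 95.8% lay within 10 kb past the 3' end of the nearest protein-coding gene, against 7.87% after shifting. Within 10 kb before its start lay 14, or 1.73%, against 8.72% after shifting, and 20 were farther away.

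Marked Zfp genes held more of their mark in the last exon than other marked genes did. In 135 marked Zfp genes the last exon held 44.0% of the covered bases and 16.8% of the gene length, and in 2394 other marked genes 11.4% and 7.35%. By chromosome, 44 of 92 Zfp genes on chromosome 7 and 13 of 24 on chromosome 8 were marked, against 8 of 36 on chromosome 13, and the chromosomes were not tested against each other. On the X, the ribosomal protein gene Rps4x had no covered base by the replicated list and 5.10% in replicate 1.

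Replicate 2 had fewer peaks than replicate 1. Lower sensitivity was predicted to let replicate 2 cover a higher share of the strongest 10% of replicate 1 peaks than of the weakest 10%. The shares were 22.2% and 4.46%, a ratio of 4.98, as predicted, though most of the strongest 10% was left uncovered. Strong peaks may recur more often than weak ones whatever the cause, so this ratio cannot decide for lower sensitivity. A different tissue make-up of the pools cannot be told apart from lower sensitivity: none of 8 lists of other tissues lay above its matched lists in either replicate (0 lists), and 7 of their 220 members were marked in replicate 1, or 3.18%. That is under the limit of 5% set for the test, which would have counted against this explanation, but its Wilson interval of 1.55 to 6.42%, brought in after the share was seen, reaches past 5% and leaves it open. The values of these lists for the replicated peaks were known when that limit was set, and cell types of the face itself and the further input files were not tested.

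Few X-linked genes carried the mark. The tables argue against gene length and GC content as the whole cause, since 10000 autosomal lists matched on both held at least 50 marked genes, against 3 on the X. Against a lack of widely transcribed genes there is weak evidence from 4 genes: among members of 6 such lists, 1 of 4 X-linked and 134 of 150 autosomal genes had a replicated peak (Fisher's exact test, two-sided, p = 0.00598), with 1 of 4 against 131 of 150 in replicate 2 (exact p = 0.00935) but 3 of 4 against 147 of 150 in replicate 1 (exact p = 0.101). A single active X copy may leave the signal under the calling threshold, and the ratio of X to autosomal genes with a covered base was 0.388 in replicate 1 and 0.0674 in replicate 2, 5.76 times apart. Any weak signal would give this and the sexes were pooled, so it cannot be told apart from other causes. Gm21887 and Mid1, which hold the peaks picked as the strongest on the X, were counted with the other X genes. Whether they have a single active copy was not tested.

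Zfp genes carried the mark more often than length-matched genes, and no biological explanation was tested. The tables argue against GC content, because matching on length and GC gave an excess of 84.7 marked genes, against 77.8 with length alone (permutation test, p = 2e-04 for each, the smallest possible). Reads shared between paralogous zinc finger exons could account for part of the excess, which fell to 27.3 with the last exon left out of every gene and stayed above matched lists (permutation test, p = 2e-04, the smallest possible). Leaving out that exon also removes 44.0% of the covered bases of marked Zfp genes, which keeps the contribution of shared reads open.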
